A study of Mus musculus with 21 samples.

How the data were processed

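The series measured gene expression in spiral ganglion neurons of mice at postnatal day 7, in 21 libraries of about 50 neurons each. The libraries were grouped by virus (control, DN-HCN2, truncated SK3) and cochlear region (apex, base) as their titles give them, which made 6 groups of 3 or 4 libraries. The labels call the libraries of a group biological replicates but do not say which animals they came from.

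The authors deposited a single table of read counts, with 1 column per library and 1 line per gene symbol. Trimmomatic, HISAT2 and DESeq2 are named without versions or settings, with the builds GRCm38 and mm10, per the submitters' processing notes. The counter and the annotation are not given there, and the counts as deposited are whole numbers that were not normalized. The table has 21878 lines, of which 3555 are at 0 in every library. In 27 lines a date stands in place of the symbol, and 2 date names are each used by 2 lines; 25 of these lines were tested under the name in the table and none is named here. Library totals ran from 10411634 to 15138780 counts.

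Genes with enough counts were kept with filterByExpr, which left 14968. Counts were scaled with TMM factors and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with 1 mean per group and all 21 libraries in the fit. Contrasts gave each construct against control in the apex, in the base and over both regions (the mean of the 2 regional effects), base against apex in each condition, the 2 interactions and the 2 constructs against each other, 12 in all. P-values were adjusted for all tested genes of a comparison by the Benjamini-Hochberg method, and a gene was called at a false discovery rate of 0.05. Levels in the text are CPM, counts divided by the TMM-scaled library total, and standard errors of log2 fold changes follow from the F statistic of each test.

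Gene symbols were matched to GENCODE M21 on GRCm38, which held 14455 of the tested symbols (96.6%), and coordinates are from that annotation. Sequence sharing of a gene is the percent of the 50-base stretches in its longest transcript that also occur in the longest transcript of another gene, with 20% as the limit for a gene said to share sequence. Such a limit cannot tell how the unnamed counter treated reads that fit 2 places.

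Gene lists of cell types, synaptic and channel families and activity or stress responses, 39 in number, were fixed before the data were examined, and 38 had at least 3 tested members. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with p-values adjusted over the 456 tests of a list in a comparison. Camera with an estimated correlation and fry were the alternatives. Counts adjusted over the list alone used the members' p-values only.

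Genes were named by a rule set in advance. For every comparison it took the genes of the 2 channels, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 CPM in the higher group, without predicted genes and pseudogenes. It added up to 4 called members of each list by smallest p, and the 5 smallest p-values where fewer than 5 genes passed. The text gives part of the genes so named, since some are not reported here, and says where a gene outside the rule was named after its values were seen.

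Alternatives planned were RLE size factors, no low-count filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, only the libraries of the groups compared, the replicate number as a block, the block within a condition, each library left out in turn, and controls divided between the 2 constructs. Alternatives chosen after seeing the data left out genes that share sequence, took out a trend on GC content and transcript length (splines with 5 degrees of freedom), left out the 2 libraries with over 1000 CPM of macrophage markers, left out the 2 libraries with over 5000 CPM of supporting cell or fibroblast markers, or averaged the regional differences over the 3 conditions. For each comparison, up to 100 divisions of the same libraries into groups of the same sizes, the real one included, were fitted in the same way.

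The code was tested on simulated data with 200 changed genes. For DN-HCN2 over both regions, edgeR recovered 7.46%, 31.3% and 59.1% of genes changed by folds of 1.5, 2 and 4, with 6 false calls among 14748 unchanged genes. For truncated SK3 over both regions it recovered 8.96%, 38.8% and 65.2%, and for base against apex in control 2.99%, 26.9% and 66.7%. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Transcript isoforms, reads over the inserts and sequence variants were not analysed here, since only the table of counts per gene was at hand.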

Results

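Spiral ganglion neurons, which carry sound signals from the cochlea to the brain, were collected from mice at postnatal day 7. About 50 neurons drawn up by micropipette made up each library, and their polyadenylated RNA was sequenced by the Smart-seq2 method. The mice had received an adeno-associated virus that carried EGFP (control), a mutated HCN2 channel with a dominant-negative action (DN-HCN2) or a truncated SK3 channel with a dominant-negative action (truncated SK3). HCN2 is a cation channel opened by hyperpolarization, and SK3, the product of Kcnn3, is a potassium channel opened by calcium. Neurons came from the apex or the base of the cochlea, which encode low and high sound frequencies. The 21 libraries comprised 4 of control apex, 4 of control base, 4 of DN-HCN2 apex, 3 of DN-HCN2 base, 3 of truncated SK3 apex and 3 of truncated SK3 base. Total counts per library ranged from 10411634 to 15138780, with group means between 11238257 ± 1126809 (SD, n = 3) in truncated SK3 base and 13957921 ± 1101021 (n = 4) in DN-HCN2 apex. Spearman correlations between libraries of a group, taken across genes, ranged from 0.947 to 0.968 in the control groups and reached down to 0.875 in DN-HCN2 base. Genes are not independent replicates, so these correlations describe the libraries only. The labels call the libraries of a group biological replicates. Errors and p-values below rest on 1 estimate of spread per gene, shared by the 6 groups. The correlations differed between groups, so these p-values need not match the spread of the groups compared. Counts from fits of only the groups compared are given as an alternative where they differed.

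Neither channel gene was called as changed. Hcn2 (chromosome 10, 79716634 to 79736108) averaged 29.02 ± 11.3 CPM (SD, n = 4) in control apex, 62.2 ± 48.6 in DN-HCN2 apex, 61.6 ± 36.6 in control base and 28.7 ± 6.68 (n = 3) in DN-HCN2 base. Over both regions its log2 fold change under DN-HCN2 was 0.00 (SE 0.59, edgeR adjusted p = 1). Kcnn3 (chromosome 3, 89520164 to 89675132) had at most 23 counts in any library, and its log2 fold change under truncated SK3 was 0.50 (SE 1.17, edgeR adjusted p = 0.949). The labels give no sequence for either insert, so these counts do not test whether the constructs were expressed. Markers of spiral ganglion neurons summed to between 13094 ± 3882 CPM (n = 3) in DN-HCN2 base and 16137 ± 635 CPM (n = 4) in control apex. Schwann and satellite glial markers were of the same order, at 24423 ± 6324 CPM (n = 4) in control base, 12471 ± 2593 (n = 3) in DN-HCN2 base and 31323 ± 15096 (n = 3) in truncated SK3 base. Macrophage markers reached 1418 and 1634 CPM in replicates 2 and 3 of DN-HCN2 base, against 27.5 CPM in replicate 1 of that group and at most 535 CPM in the 18 libraries of other groups. Supporting cell markers were highest in replicate 1 of DN-HCN2 apex at 10759 CPM, and fibroblast markers in replicate 1 of DN-HCN2 base at 8608 CPM.

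**Figure D1:**
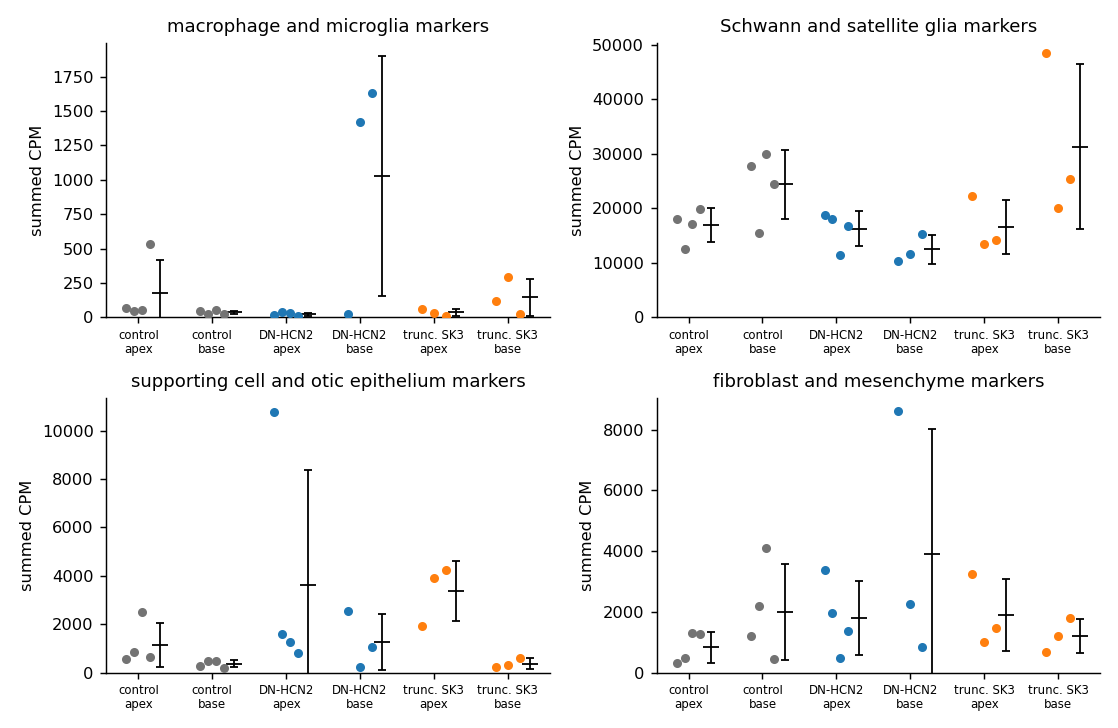
Summed CPM of marker genes of macrophages, Schwann cells, supporting cells and fibroblasts, with 1 point per library, in the 6 groups. Replicates 2 and 3 of DN-HCN2 base hold the highest macrophage sums, 1418 and 1634 CPM.

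The first question was how transcripts differed with DN-HCN2 in these neurons, whose synapses form under patterned spontaneous activity. Loss of HCN2 function was not measured here. Under DN-HCN2 the synaptic vesicle genes Syt2 and Syp fell. Syt2 (chromosome 1, 134646677 to 134762593), which encodes a vesicular calcium sensor, averaged 277 ± 20.02 CPM (SD, n = 4) in control apex and 297 ± 24.4 (n = 4) in control base, against 178 ± 65.4 (n = 4) and 114 ± 11.3 (n = 3) under DN-HCN2. Its log2 fold change over both regions was -1.01 (SE 0.15, edgeR adjusted p = 0.000485). The vesicle protein gene Syp moved from 1169 ± 183 and 1104 ± 77.3 CPM in control apex and base to 738 ± 75.5 and 549 ± 198 under DN-HCN2, a log2 change of -0.84 (SE 0.141, edgeR adjusted p = 0.00155). Under truncated SK3, too, Syt2 was lower, at 145 to 202 CPM in the apex and 159 to 239 in the base. The lowest control library was at 249 CPM. Syp lay at 803 to 880 CPM in truncated SK3 apex and 780 to 1358 in truncated SK3 base. Neither gene was called under truncated SK3 over both regions, so their falls are not particular to DN-HCN2 by these values. The axonal adhesion gene Cntn1 changed by -0.82 (SE 0.117, edgeR adjusted p = 0.000323) on the log2 scale. Transcripts of the nuclear receptor Esrrg averaged 277 ± 31.3 and 205 ± 16.2 CPM in control apex and base and 108 ± 53.6 and 61.0 ± 17.5 under DN-HCN2, a log2 change of -1.55 (SE 0.207, edgeR adjusted p = 0.000184). The immediate early gene Ier2 rose from 139 ± 43.9 and 157 ± 51.9 CPM to 312 ± 176 and 489 ± 175, a log2 change of 1.40 (SE 0.285, edgeR adjusted p = 0.00737). Each of these 5 calls also stood in all 15 fits that left out 1 library.

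Among 14968 genes tested over both regions, edgeR called 366 higher and 540 lower under DN-HCN2, or 422 higher and 353 lower with GC content and length corrected for. Falls that held in all 15 of those fits include log2 changes of -6.16 for Them5, -3.52 for Pttg1 and -3.90 for Rpl29. Rpl29 shares 47.9% of its 50-base stretches with another gene, which makes its count uncertain. Channel genes moved both ways. The potassium channel genes Kcnh5 and Kcnj3 changed by -1.74 (SE 0.259, edgeR adjusted p = 0.000485) and -2.29 (SE 0.489, edgeR adjusted p = 0.00898), while the sodium channel subunit Scn2b rose by 0.95 (SE 0.187, edgeR adjusted p = 0.00522) on the log2 scale. The count of calls was 520 without replicate 1 of control apex, 596 without replicate 4 of control apex, 566 without replicate 4 of control base and 1429 without replicate 3 of DN-HCN2 apex. DESeq2 called 1661 genes, limma-voom 1483, and edgeR 475 without the 2 libraries rich in macrophage markers, among them 308 of the 906.

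By gene group, the presynaptic lists held more falls than rises. So did the calls over all genes (540 against 366), a balance that reversed with GC content and length corrected for. The lists were not tested with that correction. Of 30 synaptic vesicle genes measured, 5 were called lower and 0 higher over all genes, and 9 were lower when adjusted over the list alone (camera adjusted p = 0.000385, adjusted p = 0.709 with an estimated correlation). Syt2, Syp and Atp6v0a1, the last at -0.74 (SE 0.133, edgeR adjusted p = 0.00269), kept their calls in all 15 fits. The active zone list had 3 of 21 members called lower, led by Lin7c at -1.10 (SE 0.168, edgeR adjusted p = 0.000593), and 5 when adjusted over the list alone (camera adjusted p = 0.00774, adjusted p = 0.709 with an estimated correlation). The other members called, Rims2 and Rims1, each kept the call in 3 of the 15 fits and had adjusted p-values of up to 0.0948 and 0.106 in edgeR without 1 library. Synaptic adhesion genes had 6 of 57 called lower, Cntn1 first, and 8 when adjusted over the list alone (camera adjusted p = 0.00649, adjusted p = 0.709 with an estimated correlation). Of 30 cadherins and protocadherins, 3 fell, with Cdh2 at -0.78 (SE 0.133, edgeR adjusted p = 0.00185), and 4 fell when adjusted over the list alone (camera adjusted p = 0.00314, adjusted p = 0.709 with an estimated correlation). Glutamate receptor and postsynaptic density genes had 4 of 39 lower, with Shank1 at -1.21 (SE 0.204, edgeR adjusted p = 0.00156), and 2 higher (camera adjusted p = 0.0621). Axon guidance genes had 3 of 60 lower, with Sema5a at -1.26 (SE 0.172, edgeR adjusted p = 0.000239), and 1 higher, Efna1, whose call stood in 3 of 15 fits (camera adjusted p = 0.0211, adjusted p = 0.709 with an estimated correlation).

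Immediate early genes went the other way. Of the 24 measured, 22 had a positive log2 fold change, with a median of 0.73, and 2, Ier2 and Egr1, were called higher over all genes against 5 adjusted over the list alone (camera adjusted p = 0.00117, adjusted p = 0.709 with an estimated correlation). Egr1 changed by 0.86 (SE 0.208, edgeR adjusted p = 0.0195) on the log2 scale and lost its call only when replicate 1 of DN-HCN2 apex and replicate 1 of DN-HCN2 base, rich in supporting cell or fibroblast markers, were both left out. Late activity-regulated genes showed no common direction (median log2 change 0.14, mean -0.11), with 1 of 23 called higher, Pim1. It was not called without replicates 1 or 2 of control apex, 1, 2 or 3 of control base, 4 of DN-HCN2 apex or 3 of DN-HCN2 base, with edgeR adjusted p-values of up to 0.0957. Cholesterol synthesis genes were lower in 21 of 24 cases, or 20 with the other scaling (RLE), and Hsd17b7 was called at -1.32 (SE 0.263, edgeR adjusted p = 0.00565) (camera adjusted p = 0.00762, adjusted p = 0.723 with an estimated correlation). Schwann cell genes had 4 of 21 called lower, and 7 when adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.709 with an estimated correlation). Supporting cell genes had 2 of 16 higher, Tectb and Fgfr3, the latter in 4 of 15 fits (camera adjusted p = 0.0155, adjusted p = 0.709 with an estimated correlation). Over the 456 tests of a list in a comparison, camera with its preset correlation called 118, while camera with an estimated correlation called 0 and had 26 unadjusted p-values under 0.05. Fry called 0 lists in a single direction, with 73 unadjusted p-values under 0.05, and 126 for a change in either direction.

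**Figure D2:**
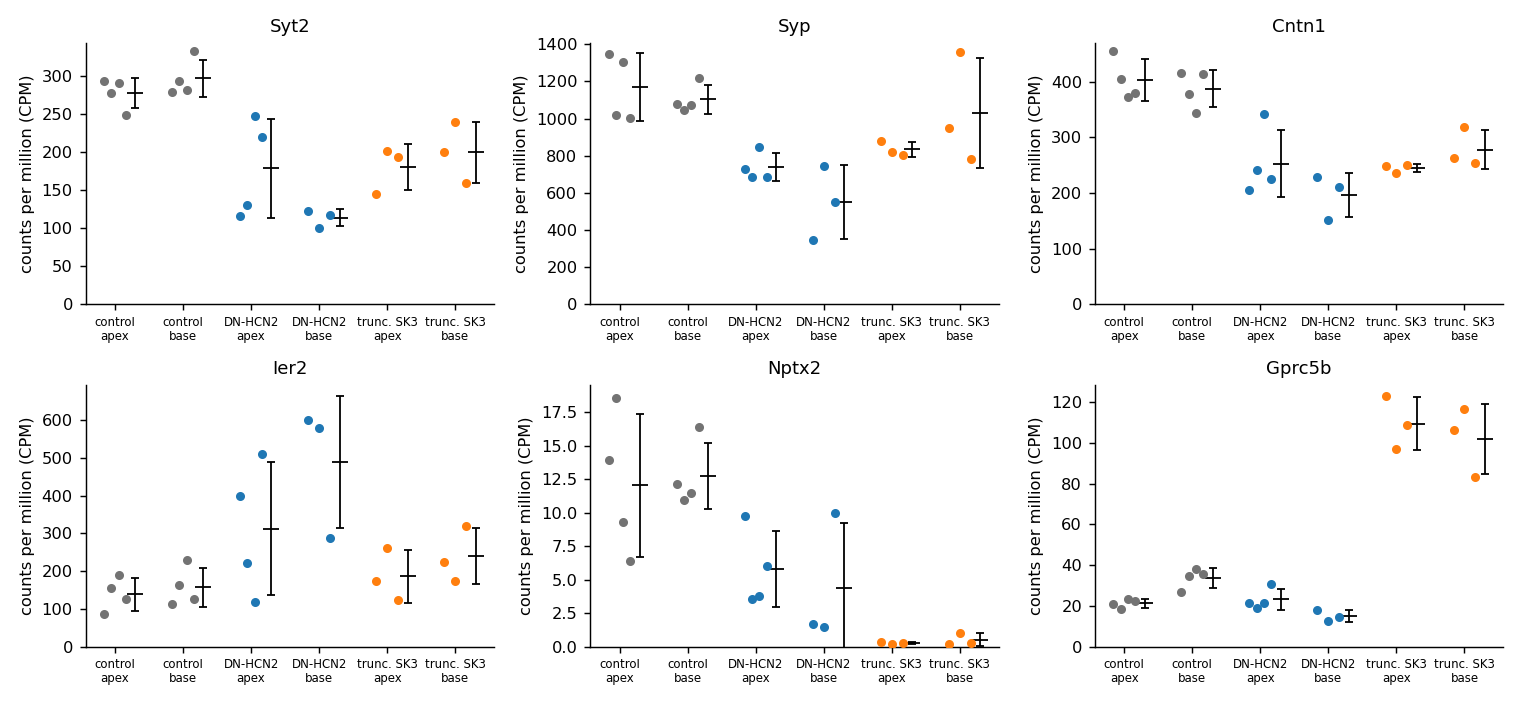
CPM of Syt2, Syp, Cntn1, Ier2, Nptx2 and Gprc5b in each library (points) of the 6 groups, with the group mean and SD (bars, ended at 0). Syt2 lies lower in the DN-HCN2 base libraries (mean 114 CPM) than in control base (mean 297 CPM), and Gprc5b is highest in the truncated SK3 libraries.

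By region, most calls were in the base. There Syt2 changed by -1.39 (SE 0.224, edgeR adjusted p = 0.0028) on the log2 scale, Cntn1 by -0.98 (SE 0.174, edgeR adjusted p = 0.00553) and Sema5a by -1.94 (SE 0.262, edgeR adjusted p = 0.000508), each called in all 7 fits without 1 library. These calls ended when the 2 libraries rich in macrophage markers were both left out, which leaves 1 DN-HCN2 base library; the log2 changes were then -1.25 for Syt2, -0.74 for Cntn1 and -1.55 for Sema5a (edgeR adjusted p = 0.104, 0.175 and 0.0739). Esrrg fell in the base by 1.75 (SE 0.31, edgeR adjusted p = 0.00553) and in the apex by 1.36 (SE 0.276, edgeR adjusted p = 0.0389), the latter called in 1 of 8 fits without 1 library, the one without replicate 3 of DN-HCN2 apex. Its base call, too, ended without the 2 libraries rich in macrophage markers, at a log2 change of -1.34. In the base edgeR called 126 genes higher and 194 lower, against 179 and 179 with GC content and length corrected for and 271 and 183 by limma-voom. In the apex it called 10 higher and 20 lower. Of the apex calls, 13 of 28 with a value share at least 20% of their 50-base stretches with another gene, against 5.71% of tested genes. Apex calls without such sharing that stood in all 8 fits include Hddc3, with a log2 change of 1.53 (SE 0.239, edgeR adjusted p = 0.00286), Map3k1 with -1.63 (SE 0.191, edgeR adjusted p = 7.49e-05), Cox15 and Them5. Macrophage genes were higher in the base, with 2 of 15 called, Cd68 and Csf1r, and 11 when adjusted over the list alone (camera adjusted p = 3.29e-06, adjusted p = 0.709 with an estimated correlation). Both were called in 2 of 7 fits and ended without replicate 2 of DN-HCN2 base (edgeR adjusted p = 0.133 and 0.0668). Csf1r was at 454 and 227 CPM in replicates 2 and 3 of DN-HCN2 base and at 2.41 CPM in replicate 1. Cholesterol synthesis genes had 4 of 24 called lower in the base, among them Hsd17b7, called in 5 of the 7 fits, and Hmgcs1 and Cyp51, each called in 1 (camera adjusted p = 9.06e-07, adjusted p = 0.709 with an estimated correlation). Schwann and satellite glial markers moved with them, at 12471 CPM in DN-HCN2 base against 24423 in control base.

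The base count was 165, 153, 172 and 107 without replicates 1 to 4 of control base in turn, and 569, 165 and 171 without replicates 1 to 3 of DN-HCN2 base. The apex count was 18 and 19 without replicates 2 and 4 of control apex, and 16 and 86 without replicates 1 and 3 of DN-HCN2 apex. Whether the DN-HCN2 effect differed between base and apex was tested as an interaction. It called 1 gene, the macrophage gene Adgre1, at 18.2 ± 22.1 CPM (SD, n = 3) in DN-HCN2 base and 5.21 ± 7.32 CPM (n = 4) in control apex, and under 1 CPM on average in the other groups (interaction edgeR adjusted p = 0.0278; 1026 unadjusted p-values under 0.05 over all genes). The call stood in 4 of 15 fits without 1 library, with adjusted p-values of up to 0.167, and ended without the 2 libraries rich in macrophage markers. For the interaction DESeq2 called 123 genes and limma-voom 0.

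Fewer genes were called under truncated SK3 than under DN-HCN2. Nptx2 (chromosome 5, 144545902 to 144557478), a secreted synaptic protein gene regulated by activity, averaged 12.1 ± 5.36 CPM (SD, n = 4) in control apex and 12.7 ± 2.49 (n = 4) in control base, against 0.273 ± 0.0707 (n = 3) and 0.514 ± 0.465 (n = 3) under truncated SK3. Over both regions its log2 fold change was -5.00 (SE 0.597, edgeR adjusted p = 5.25e-05). Gprc5b (chromosome 7, 118972047 to 118995211), an orphan receptor gene, rose from 21.1 ± 2.07 to 109 ± 13.03 CPM in the apex and from 33.8 ± 4.88 to 102 ± 17.2 in the base. Its log2 changes were 2.37 (SE 0.207, edgeR adjusted p = 7.96e-07) in the apex and 1.59 (SE 0.203, edgeR adjusted p = 0.000243) in the base. Csrp1 (chromosome 1, 135720061 to 135752232) rose by 3.60 (SE 0.367, edgeR adjusted p = 7.82e-06) over both regions and Psmc3ip (chromosome 11, 101091823 to 101095436) by 3.36 (SE 0.389, edgeR adjusted p = 3.74e-05). Shank1, a scaffold gene of the postsynaptic density, went from 44.0 ± 6.61 and 35.8 ± 5.04 CPM in control apex and base to 14.2 ± 4.75 and 14.2 ± 5.32, a log2 change of -1.49 (SE 0.216, edgeR adjusted p = 0.000549). The sodium channel subunit Scn4b rose by 1.57 (SE 0.255, edgeR adjusted p = 0.00239). All but Gprc5b, which was named by region, held their calls over both regions in all 14 fits without 1 library. Shank1, Csrp1 and Scn4b were called in the same direction under DN-HCN2 too, at log2 changes of -1.21, 1.60 and 0.90 over both regions.

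Over both regions edgeR called 49 genes higher and 61 lower under truncated SK3, of which 18.3% share sequence with another gene. Of the 49 higher, 30 were called higher under DN-HCN2 too, and of the 61 lower, 34 were called lower. Most of these calls are therefore not particular to truncated SK3. Late activity-regulated genes had Nptx2 called lower and Syt4 higher among 23 (camera adjusted p = 0.947; median log2 change 0.09, mean -0.38). Syt4 rose by 0.70 (SE 0.137, edgeR adjusted p = 0.0133) and was not called without replicate 3 of truncated SK3 base (edgeR adjusted p = 0.059). Of 30 synaptic vesicle genes, 1, Rab3c, was called lower, and 3 when adjusted over the list alone (camera adjusted p = 0.0407, adjusted p = 0.709 with an estimated correlation). Rab3c was not called without replicate 1 of control apex, 4 of control base, 1 or 2 of truncated SK3 apex, or 1 or 3 of truncated SK3 base, with edgeR adjusted p-values of up to 0.0828. Of 57 synaptic adhesion genes, Cntn1 alone was called, at -0.60 (SE 0.121, edgeR adjusted p = 0.0164), and it lost the call without replicate 1 or 3 of truncated SK3 base (edgeR adjusted p = 0.0611 and 0.0602). Immediate early genes had a positive log2 change in 20 of 24 cases, and edgeR called 0 of them over all genes or over the list alone (camera adjusted p = 0.00957, adjusted p = 0.742 with an estimated correlation). The count of calls was 72 without replicate 1 of control apex, 72 without replicate 1 of truncated SK3 base and 61 without replicate 3 of truncated SK3 base. DESeq2 called 320 genes, limma-voom 305, and edgeR 244 with only the control and truncated SK3 libraries in the fit.

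Single regions gave fewer calls. In the apex edgeR called 15 genes higher and 23 lower (limma-voom 73 and 46), among them Gprc5b, Psmc3ip, Csrp1 and the fall of Car10, -2.62 (SE 0.372, edgeR adjusted p = 0.00108). In the base it called 11 higher and 11 lower, with Csrp1 at 3.88 (SE 0.523, edgeR adjusted p = 0.000651) and Psmc3ip, which was not called without replicate 3 of truncated SK3 base (edgeR adjusted p = 0.0587). Nptx2 fell in both regions, by 5.42 (SE 0.867, edgeR adjusted p = 0.00365) in the apex and by 4.58 (SE 0.822, edgeR adjusted p = 0.0126) in the base. The apex fall was not called without replicate 2 of truncated SK3 apex (edgeR adjusted p = 0.0504), nor the base fall without replicate 1 or 3 of truncated SK3 base (edgeR adjusted p = 0.159 and 0.14). Of the base calls, 11 of 22 share sequence with another gene, among them Dynlt1b, Eno1b and Rpl26. The apex count was 23, 25 and 24 without replicates 1 to 3 of control apex, and 62, 19 and 22 without replicates 1 to 3 of truncated SK3 apex; the base count was 11 and 12 without replicates 1 and 3 of truncated SK3 base. For a different effect in base and apex, edgeR called 0 genes, with 545 unadjusted p-values under 0.05, limma-voom called 0 and DESeq2 called 21.

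To see whether the constructs act on common genes, their calls over both regions were set side by side. Shank1, Them5, Pttg1 and Rpl29 fell under both, and Hddc3, Ly6e, Eno1b and Dynlt1b rose under both. In all, 30 genes were called higher and 34 lower in both comparisons, and 1 gene went opposite ways. That gene, Gprc5b, rose under truncated SK3 and fell under DN-HCN2 by 0.52 (SE 0.141, edgeR adjusted p = 0.0332) over both regions, in 5 of 15 fits without 1 library, and by 1.17 (SE 0.212, edgeR adjusted p = 0.0058) in the base, in 7 of 7. In the apex Gprc5b was not called under DN-HCN2, at 0.13 (SE 0.19, edgeR adjusted p = 0.876), so the fall rests on the base. Independent lists of these sizes would share 1.2 genes higher and 2.2 lower. In 20 simulations of unchanged groups against the same 8 controls, 0 of each were shared. The simulated libraries were drawn around the means of these same controls, and unchanged groups leave few calls to share. The simulations therefore cannot measure what the shared controls add to the overlap or to the correlation below. With the controls divided between the comparisons in 6 ways, 8 to 9 genes were higher and 15 to 17 lower in both. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.466, against 0.194 to 0.249 in the simulations, and a covariance of 0.431, against a simulated median of 0.0804. With the controls divided, the correlation was 0.193 to 0.281 and the covariance 0.241 to 0.334. Of 63 genes called alike with a value, 17 share at least 20% of their 50-base stretches with another gene (one-sided Fisher's exact p = 5.19e-08 against the other tested genes). Rpl29 fell from 113 ± 10.9 CPM in control apex to 8.41 ± 0.469 in DN-HCN2 apex, while its near-copy Gm8210, named after its values were seen, stood at 0.130 and 19.7 ± 1.36 CPM. Such pairs leave open which copy the reads came from.

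**Figure D3:**
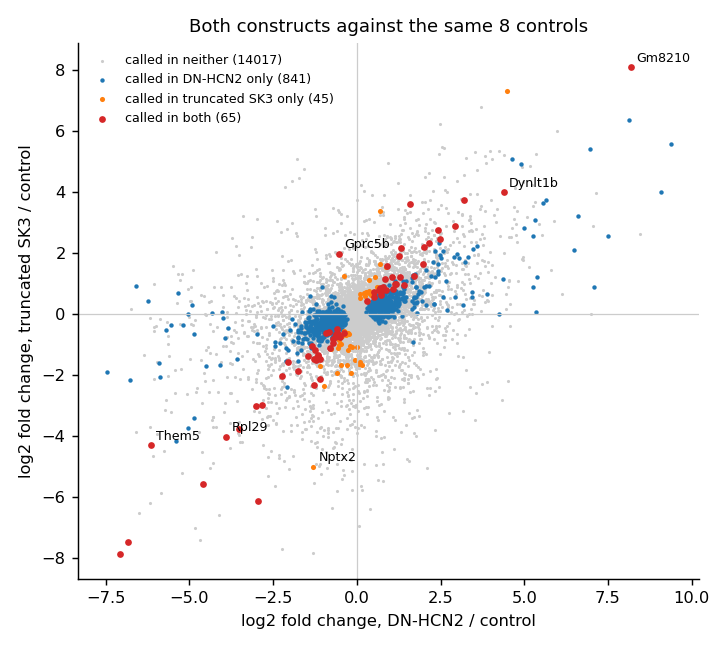
Log2 fold change against control over both regions of 14968 genes under DN-HCN2 (x axis) and truncated SK3 (y axis), coloured by the comparisons in which edgeR called the gene. Genes called in both number 65, and 841 were called under DN-HCN2 only and 45 under truncated SK3 only.

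The constructs were also compared with each other over both regions. Gprc5b was lower under DN-HCN2 than under truncated SK3 by a log2 change of -2.50 (SE 0.156, edgeR adjusted p = 5.98e-09), and Nptx2 was higher, at 3.70 (SE 0.572, edgeR adjusted p = 0.00418). Lin7c was lower under DN-HCN2 than under truncated SK3, at -1.06 (SE 0.177, edgeR adjusted p = 0.00801). So were Psmc3ip and Csrp1, though Csrp1 rose against control under both, by log2 changes of 1.6 (DN-HCN2) and 3.6 (truncated SK3). Each of these 5 calls stood in all 13 fits without 1 library. The kinase gene Pim1, of the late activity-regulated list, was higher by 2.59 (SE 0.518, edgeR adjusted p = 0.0208) and was not called without replicate 2 of truncated SK3 apex or of truncated SK3 base (edgeR adjusted p = 0.0598 and 0.0619). Schwann cell genes were lower under DN-HCN2 than under truncated SK3 in 21 of 21 cases, or 20 with RLE scaling, and 6 were called when adjusted over the list alone (camera adjusted p = 3.88e-08, adjusted p = 0.709 with an estimated correlation). In total edgeR called 33 genes higher and 65 lower (40 and 49 with GC content and length corrected for), and the count was 354 without replicate 3 of DN-HCN2 apex, 206 without replicate 1 of DN-HCN2 base, and 52 and 260 without replicates 1 and 3 of truncated SK3 base. With only these 13 libraries in the fit it was 7, DESeq2 called 540, and another split of the 13 libraries gave 665.

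The last question was how neurons of the base differ from those of the apex within each condition. In control libraries the apex-enriched genes with the smallest p-values were Chrna4, a nicotinic receptor subunit gene, and Kcnip4 (chromosome 5, 48389502 to 49524907), which encodes a subunit of A-type potassium channels. Chrna4 averaged 46.0 ± 13.1 CPM (SD, n = 4) in the apex and 10.7 ± 4.97 (n = 4) in the base, with a log2 change from apex to base of -2.10 (SE 0.371, edgeR adjusted p = 0.209). Kcnip4 averaged 25.4 ± 9.83 and 4.14 ± 3.12 CPM, with -2.62 (SE 0.512, edgeR adjusted p = 0.228), so neither passed. For control libraries edgeR called 0 genes, with 722 unadjusted p-values under 0.05, against 83 genes by DESeq2 and 40 by limma-voom. Hair cell genes were lower in the base in 16 of 16 cases, and edgeR called 8 of them lower when adjusted over the list alone (camera adjusted p = 5.43e-12, adjusted p = 0.709 with an estimated correlation). All 24 cholesterol synthesis genes were higher in the base, none of them called over all genes or the list alone (camera adjusted p = 3.01e-12, adjusted p = 0.709 with an estimated correlation). Schwann and satellite glial markers, too, were higher in control base, at a sum of 24423 CPM against 16957 in control apex. Summed hair cell markers were 787 ± 669 CPM (n = 4) in control apex and 192 ± 29.9 CPM (n = 4) in control base.

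Under DN-HCN2 the regional difference in Kcnip4 passed the test. It averaged 45.6 ± 23.6 CPM (SD, n = 4) in the apex and 0.813 ± 0.0707 (n = 3) in the base, a log2 change of -5.79 (SE 0.691, edgeR adjusted p = 0.000676). Its relative Kcnip1 went the other way, from 60.5 ± 6.08 to 158 ± 30.9 CPM and a log2 change of 1.39 (SE 0.18, edgeR adjusted p = 0.00126), and Lancl3 was lower in the base by -1.83 (SE 0.277, edgeR adjusted p = 0.00838). These 3 calls stood in all 7 fits without 1 library, and those of Kcnip4 and Kcnip1 ended without the 2 libraries rich in macrophage markers, at log2 changes of -5.67 and 1.08 (edgeR adjusted p = 0.074 and 0.084). Here limma-voom called 0 genes, edgeR with only these 7 libraries called 0 and DESeq2 called 379, beside 1806 unadjusted p-values under 0.05 in edgeR on all libraries. In all, edgeR called 17 genes higher and 15 lower in the base, with the macrophage genes Oscar, Adgre1, Spi1 and Cd68 among the higher ones. The count was 138, 8, 4 and 6 without replicates 1 to 4 of DN-HCN2 apex and 178, 10 and 10 without replicates 1 to 3 of DN-HCN2 base, and another split of the 7 libraries gave 554. Under truncated SK3 edgeR called 2 genes, Kcnip4, at 58.6 ± 10.1 CPM in the apex and 4.40 ± 2.73 in the base with a log2 change of -3.74 (SE 0.619, edgeR adjusted p = 0.044), and Sh2d6. Kcnip1 was higher in the base by 0.99 (SE 0.195, edgeR adjusted p = 0.12) and did not pass. Both calls held in 1 of 6 fits, the one without replicate 1 of truncated SK3 apex, which called 26 genes. Without replicate 3 of truncated SK3 apex the count was 1, and without any of the other 4 libraries it was 0.

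**Figure D4:**
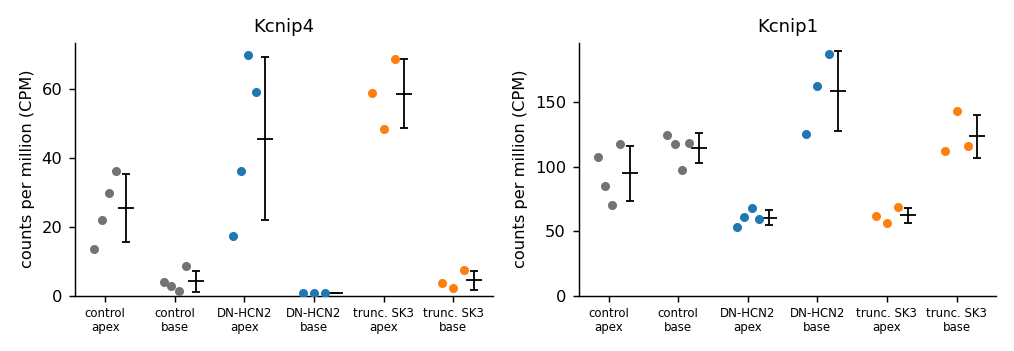
CPM of Kcnip4 and Kcnip1 in each library (points) of the 6 groups, with the group mean and SD (bars, ended at 0). Kcnip4 means lie at 25.4, 45.6 and 58.6 CPM in the apex of control, DN-HCN2 and truncated SK3 and at 4.14, 0.813 and 4.40 CPM in the base.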

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

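The tests of shared reads, genetic background, GC content and length, macrophage RNA and neuron share, and the splits for base against apex over the 3 conditions, were chosen after the result was seen; the other splits were planned.

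A library was flagged where it lay far from the other 3 of its group. Of 117 groups of values tested this way 10 were flagged, and chance alone flags about 1 in 20, here 5.85. Summed supporting cell markers were 2496 CPM in replicate 3 of control apex (others 542 to 858) and 10759 CPM in replicate 1 of DN-HCN2 apex (others 807 to 1615). Endothelial markers were 172 CPM in replicate 4 of DN-HCN2 apex (others 20.2 to 42.5), and macrophage markers 535 CPM in replicate 4 of control apex (others 46.1 to 66.9). Red blood cell markers were 1936 CPM in replicate 2 of DN-HCN2 apex (others 17.7 to 80.7), and spiral ganglion neuron markers 17087 CPM in replicate 1 of control apex (others 15747 to 15860). Lin7c was at 25.6 CPM in replicate 4 of DN-HCN2 apex (others 53.9 to 58.6), Shank1 at 34.2 CPM in replicate 3 of control apex (others 46.0 to 48.2), Gm8210 at 0.0704 CPM in replicate 4 of control base (others 0) and Adgre1 at 0.0829 CPM in replicate 3 of DN-HCN2 apex (others 0). Adgre1 was also flagged because its DN-HCN2 effect differed between base and apex in the interaction test, with a fitted log2 difference of 16.11; with group means near 0 CPM in the comparison, that figure is no measure of size.

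Genes that moved the same way under both constructs number 64, and all 8 control libraries lie apart from all 13 others for 33 of them. Reads shared between near-identical copies do not account for the pattern as a whole, since 27% of the genes share sequence. Of the 17 genes that do share sequence, 5 have a copy called in the opposite direction under both constructs, as reads moved between copies would give. They are the pairs Rpl29 with Gm8210 and Tagap with Tagap1, and Rpl34-ps1 (Gm8210, Tagap1 and Rpl34-ps1 were named after their values were seen). Sharing alone would act on control and treated libraries alike, so it does not say why these groups differ. A sequence difference between control and treated animals could also move reads between copies, and these values do not exclude it. For the rest of the 17, among them Dynlt1b, Eno1b and Rnaset2a, no tested copy was called in the opposite direction. A different genetic background of control and treated animals cannot be told apart from an effect of the constructs: 9 of the genes without shared sequence lie within 2 Mb of another, against a median of 6 in 10000 random draws (permutation p = 0.132). That test left out genes that share sequence, among them Dynlt1b, Tagap1, Tagap and Rnaset2a, which lie between 6430112 and 8148097 on chromosome 17. It therefore says nothing about that cluster or about the copies called in opposite directions. An effect common to both dominant-negative channels stays open as untested.

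For DN-HCN2 over both regions the 906 calls had a median log2 change, signed by direction, of 0.87. With the trend on GC content and length taken out the median was 0.725, with 515 genes still called and 905 in the same direction, which argues against that bias as the whole cause. Without the 2 libraries rich in macrophage markers, which leaves 1 DN-HCN2 base library, the median was 0.834, with 905 in the same direction. The genes were picked on all libraries, and most of these stay in that fit, so their direction was likely to hold in any case. How much macrophage RNA adds to the list therefore stays open. A lower share of neurons with an unchanged mix of other cells would raise the markers of those cells alike. Supporting cell markers instead rose relative to Schwann cell markers by a log2 difference of 1.74 (SE 0.664). That mix varied between libraries, with supporting cell markers at 807 to 10759 CPM within DN-HCN2 apex, so the difference cannot exclude a lower share of neurons. Summed neuron markers changed by -0.0841 (SE 0.109) on the log2 scale. An effect of DN-HCN2 on these neurons, or on the mix of cells taken up with them, stays open as untested.

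Macrophage markers were high in replicates 2 and 3 of DN-HCN2 base. Macrophages taken up with the neurons have the values they need, since 15 of 24 macrophage genes outside the list that picked the 2 libraries were higher in both than in all 19 others. A lower share of neurons with an unchanged mix of other cells would raise Schwann cell and macrophage markers alike. Against control base their log2 changes in the 2 libraries were -0.823 (SE 0.339) and 5.46 (SE 0.398), a difference of 6.28 (SE 0.281). Whether more macrophages gather in the ganglion under DN-HCN2, or were drawn up in these 2 libraries by the way of collection, was not tested, and replicate 1 of that group had 27.5 CPM.

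Other splits of the same libraries show where the groups themselves account for a count. The real grouping gave the most calls, with 1 split as large (itself), for DN-HCN2 in the apex (30 against a highest other of 2), in the base (320 against 6) and over both regions (906 against 57), and for truncated SK3 in the apex (38 against 2), in the base (22 against 17) and over both regions (110 against 7). With 35 splits in each single region and 100 over both, chance is an unlikely source of these counts. So few splits cannot exclude it, least of all for truncated SK3 in the base. The same holds for base against apex over the 3 conditions, with 173 against 63 and 1 split as large. Chance could well give the counts of the DN-HCN2 interaction (1 gene, 6 of 100 splits as large), base against apex in DN-HCN2 (32 genes, 6 of 35) and DN-HCN2 against truncated SK3 (98 genes, 5 of 100). With 0 genes called, every split is as large by necessity, so the splits say nothing about chance for base against apex in control (35 of 35) or for the truncated SK3 interaction (100 of 100, highest other 8). In these 3 comparisons another split called several times the real count, with a highest of 554 for base against apex in DN-HCN2, 462 for the DN-HCN2 interaction and 665 for DN-HCN2 against truncated SK3. What sets those splits apart was not tested. For base against apex in truncated SK3 (2 genes, 2 of 10 splits as large, highest other 51) there are too few splits to tell about chance. Counts of gene lists called by camera could arise by chance, with 46 of 100 splits as large for DN-HCN2 (highest other 18), 22 of 100 for truncated SK3 (highest other 24) and 6 of 35 for base against apex in control (highest other 19).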

How the results depend on the processing

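Alternatives on shared sequence, GC content and length, the libraries rich in macrophage, supporting cell or fibroblast markers, and the mean over 3 conditions were chosen after seeing the data; the others were planned. Of 241 calls of named genes, 234 were kept with RLE size factors, 203 without a filter, 225 of 225 with the stricter filter, 236 with DESeq2, 157 with limma-voom, 153 of 235 with only the groups compared, 163 with the replicate block, 190 of 199 without genes that share sequence, 214 with GC and length correction, 133 of 180 without the libraries rich in supporting cell or fibroblast markers and 46 of 161 without those rich in macrophage markers; 109 stood in all fits without 1 library. Without the macrophage-rich libraries DN-HCN2 base is 1 library, assumed to vary like the others, and 2 of its log2 changes reversed, Mmp9 to -0.23 and Csf1r to -0.11. Calls of gene lists, 118 with preset correlation, were 0 with an estimated correlation and 0 with fry. Where a count below differs from the main one, the cause was not tested, except that leaving out libraries or genes leaves fewer of them. At this depth and number of libraries, edgeR recovered under 10% of simulated changes of 1.5-fold in each comparison.

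Counts are given in the order DN-HCN2 apex, base, both regions; truncated SK3 apex, base, both; base against apex in control, DN-HCN2, truncated SK3; interactions of DN-HCN2 and truncated SK3; the 2 constructs compared; genes called alike in both; base against apex over the 3 conditions. The main counts were 30, 320, 906; 38, 22, 110; 0, 32, 2; 1, 0; 98; 64; 173. DESeq2 gave 232, 1101, 1661; 156, 81, 320; 83, 379, 212; 123, 21; 540; 158; 571. Limma-voom gave 212 (DN-HCN2 apex), 1483 (both), 119, 45 and 305 (truncated SK3), 40, 0 and 0 (regions), 0 (DN-HCN2 interaction), 151 (called in both) and 79 (3 conditions).

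Without genes that share sequence the counts were 8 (DN-HCN2 apex), 22 and 10 (truncated SK3 apex and base) and 42 (called in both). With only the groups compared they were 244 (truncated SK3 both), 37, 0 and 0 (regions), 7 (constructs) and 109 (called in both). No filter gave 18 for base against apex in DN-HCN2, and GC and length correction 5 for truncated SK3. That correction gave 54.5% higher calls for DN-HCN2 over both regions (main 40.4%) and 50% in the base (main 39.4%). Without the macrophage-rich libraries the counts were 103 (DN-HCN2 base, 34 of the main calls kept), 475 (both), 16 (base against apex in DN-HCN2), 0 (interaction), 52 (constructs) and 41 (3 conditions). Without the libraries rich in supporting cell or fibroblast markers they were 866, 551 (base against apex in DN-HCN2), 64 (interaction) and 480 (3 conditions). With controls divided in 6 ways, 25, 26, 24, 24, 24 and 23 genes were called in both.

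Libraries share replicate numbers, but the labels say nothing of a shared animal or batch. Deviations of same-numbered apex and base libraries correlated at -0.0749 to 0.132 (2 of 10 above 0.1), so the numbers were not taken to pair them. As a hint from the data, 11 of 20 libraries correlated best with their own number, where 5.75 are due by chance. With the replicate block the counts were 141 (DN-HCN2 base), 602 (both), 69 (truncated SK3 both), 4 and 1 (base against apex in DN-HCN2 and truncated SK3), 0 (DN-HCN2 interaction) and 80 (3 conditions). With the block within condition they were 6, 3 and 11 (regions), 0 (DN-HCN2 interaction) and 75 (3 conditions).

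Leaving out 1 library at a time gave 16 to 86, 107 to 569 and 520 to 1429 for DN-HCN2 apex, base and both; 19 to 62, 11 to 22 and 61 to 114 for truncated SK3; 0 to 2, 4 to 178 and 0 to 26 for the regions in control, DN-HCN2 and truncated SK3; 0 to 34 for the DN-HCN2 interaction, 52 to 354 for the 2 constructs, 44 to 79 for genes called in both, and 55 to 282 for the 3 conditions.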

Other observations

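Averaging the difference between base and apex over the 3 conditions, a comparison chosen after seeing the data, set 11 apex against 10 base libraries. In edgeR it called more genes than any single condition did. The A-type potassium channel subunit gene Kcnip4 was lower in the base by a log2 change of -4.05 (SE 0.352, edgeR adjusted p = 3.08e-06), while its relative Kcnip1 was higher by 0.88 (SE 0.105, edgeR adjusted p = 0.000306). The nicotinic receptor gene Chrna4 was lower in the base at -1.86 (SE 0.232, edgeR adjusted p = 0.000481). Higher in the base were the adhesion gene Adgrl2 at 1.28 (SE 0.186, edgeR adjusted p = 0.00233), the ephrin receptor gene Ephb1 at 1.51 (SE 0.246, edgeR adjusted p = 0.00461), Amigo2 at 1.95 (SE 0.291, edgeR adjusted p = 0.00233) and Fam43b at 2.71 (SE 0.395, edgeR adjusted p = 0.00233). Myh7b was lower at -1.23 (SE 0.183, edgeR adjusted p = 0.00233) and Colq at -1.56 (SE 0.239, edgeR adjusted p = 0.00271); Amigo2, Fam43b, Myh7b and Colq were named after their values were seen. All 9 kept their calls in the 21 fits that left out 1 library and in every other setting tried. Kcnip4 had the same sign in control (-2.62), DN-HCN2 (-5.79) and truncated SK3 (-3.74), as had 169 of the 173 genes called (86 higher and 87 lower in the base). The genes were picked on the mean of these same 3 differences, so a common sign was likely in any case and adds no evidence.

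By group, hair cell genes were lower in the base in 16 of 16 cases, with 7 called over all genes and 12 adjusted over the list alone (camera adjusted p = 9.54e-12, adjusted p = 0.355 with an estimated correlation). Of the 7, the calls of Pou4f3, Ocm, Chrna10 and Otof stood in 18, 16, 15 and 15 of 21 fits without 1 library, with the highest adjusted p-values in edgeR (0.0619, 0.0841, 0.087 and 0.087) without replicate 1 of truncated SK3 base. All 4 ended with limma-voom and without the 2 libraries rich in macrophage markers. Of 38 voltage-gated potassium channel genes, 3 were called lower and 2 higher in the base, with Kcnab1 at -1.66 (SE 0.304, edgeR adjusted p = 0.011) and Kcnip2 at 0.74 (SE 0.142, edgeR adjusted p = 0.0154) (camera adjusted p = 0.00296, adjusted p = 0.355 with an estimated correlation). The calls of Kcnab1 and Kcnip2 ended without those 2 libraries, and Kcnip2 also with the block within condition. Cadherins and protocadherins showed no common direction (17 of 30 lower with a median log2 change of -0.10, camera direction up, camera adjusted p = 0.577, adjusted p = 0.725 with an estimated correlation), with 3 called higher in the base over all genes, and 4 higher and 3 lower adjusted over the list alone. Among the 3 were Cdh22 at 2.01 (SE 0.343, edgeR adjusted p = 0.00621) and Pcdh9 at 1.55 (SE 0.29, edgeR adjusted p = 0.0151), which ended without those 2 libraries as well.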
